A study of Homo sapiens with 1395 samples.

How the data were processed

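RNA was measured in formalin-fixed, paraffin-embedded kidney transplant biopsies with the Banff Human Organ Transplant panel (B-HOT) on the NanoString nCounter, an instrument that counts barcoded probes hybridized to RNA without amplification. Per the labels, 2 curls of 16 micrometres were taken from each block and RNA was extracted by hand or on a robot with Zymo kits. The panel holds 770 features, of which 12 are housekeeping genes and 758 are targets, among them 4 probes for viral transcripts. The series holds 1395 samples in 4 diagnoses, and the labels place each sample in a discovery or a validation cohort. Features are identified by the panel's gene symbols, and no probe positions or genome coordinates come with the table.

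The deposited values are log2 values scaled per sample by the authors. The mean log2 value of the 12 housekeeping genes lay between 8.396 and 8.397 in every sample. The floor of the table was -2, which is log2 of 0.25, and 1590 of the 1074150 values sat on it. Within each sample the lowest levels, taken out of the log2 scale and less 0.25, were whole multiples of a single step, so the values are log2 of a count times a scaling factor plus 0.25. All values from 1 to under 100 counts came out whole within a tolerance of 0.05. The software, its version and the handling of background and control probes are not given in the sources used here. The step, called the scaling factor from here on, gave back each sample's total count, which ranged from 48050 to 1181117 with a median of 417268.

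Comparisons were fitted with limma 3.58.1 in R 4.3.3 on the deposited log2 values of the discovery cohort, with the 4 diagnoses in a single fit, moderated variances with a mean trend, two-sided tests and Benjamini-Hochberg adjustment over the 758 targets of each comparison. A gene was called at an adjusted p under 0.05 with a change of at least 1.5-fold. The 7 comparisons were each rejection group against no rejection, the 3 pairs of rejection groups, and the departure of mixed rejection from the sum of the AMR and TCMR changes on the log2 scale. The same fit was run in the validation cohort alone, and a cohort-by-diagnosis term tested the difference between cohorts over all samples. No count model was fitted.

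Each comparison was summarised over 25 gene lists: T cells, NK cells, cytotoxic effectors, interferon-gamma response, type I interferon response, endothelium, AMR genes of earlier studies, TCMR genes of earlier studies, B cells, plasma cells and immunoglobulin, monocytes and macrophages, dendritic cells, neutrophils, mast cells and eosinophils, regulatory and follicular T cells, immune checkpoints, MHC class I presentation, MHC class II presentation, chemokines, complement, kidney injury and repair, tubular epithelium, podocytes and glomerulus, fibrosis and extracellular matrix, and toll-like receptors and inflammasome. The viral probes and the housekeeping genes were summarised separately. The lists of earlier studies were written from knowledge of the transplant literature, and none was chosen on these samples. Lists share members: 35 of the 36 measured AMR genes, 25 of the 31 TCMR genes, 20 of the 37 endothelial genes and 15 of the 27 interferon-gamma response genes also stand in another list. Lists were tested against the other targets with camera (limma) at a preset inter-gene correlation of 0.01 and again with the correlation estimated from the data, and each list's median less the median of all targets was set beside that of 100 splits of the samples into groups of the same sizes, the real one included.

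A score per list, the mean of its members scaled to the no-rejection samples of the discovery cohort, was compared between groups by the area under the receiver operating curve (AUC) with 100000 permutations in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. A multinomial lasso (glmnet 4.1-10) with class weights and a penalty chosen by 10-fold cross-validation was trained on the discovery cohort and applied to the validation cohort, beside 100 trainings on permuted labels. Shares carry Wilson 95% intervals. The genes called in both AMR and TCMR were counted beside 100 simulated sets of unchanged groups and with the no-rejection samples split at random between the comparisons, since both share their controls. Figures were drawn with matplotlib 3.10.9. The fit was tested on simulated data with the sample numbers of both cohorts: of genes shifted 2-fold, 98.5 to 100% were called in the discovery cohort and 89.6 to 100% in the validation cohort, and no unshifted gene was called. Without the fold minimum, 1, 16 and 53 of 558 unshifted genes had an adjusted p under 0.05 in AMR, TCMR and mixed rejection against no rejection in the discovery cohort. In the validation cohort 0, 1 and 0 did so. Of genes shifted exactly 1.5-fold, 34.3 to 62.7% were called.

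Before the data were examined, the samples of each group, the tests, the thresholds, the gene lists and a rule for the genes to name were fixed. The rule took the 10 largest increases and the 6 largest decreases among genes called in discovery with the same sign and an adjusted p under 0.05 in validation, up to 4 members with the largest change of each list described, and CXCL9, CXCL11, GNLY, PLA1A, ROBO4, KLRF1, SH2D1B, ADAMDEC1, CXCL13, CTLA4 and IFNG in comparisons against no rejection. Its first part returned 0 genes, because no gene reached that p in the validation cohort. Alternatives fixed at the same time were the joint fit of both cohorts, fits with only the compared groups, re-centring of each sample on the housekeeping genes or on the median of all targets, quantile normalization, removal of the lowest 25% of genes, other variance models (no trend, robust, array weights), a Wilcoxon rank-sum test, fold minimums, and other forms of the list tests and the classifier. Added after seeing the data were the scaling factor as a covariate, removal of the 5% of samples with the largest scaling factor, a block for each run of 100 of the numbers in the sample titles, the cross-validation of the classifier within the discovery cohort, the list medians over other splits of the samples, splits of the labels within these runs, and the comparison of the classifier's calls with the validation labels in other orders. The splits within runs were first run with all 4 groups in the fit and were replaced by fits of the compared groups alone, since links through the other groups remain in the first form. No sample was left out of the comparisons, and no pair of samples was nearly identical (highest correlation between any 2 samples 0.894). Counts of molecules limit the precision of low-count targets: 140 of the 758 targets had a median of under 20 counts and 74 a median of under 10.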

Results

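The data are RNA counts from 1395 archived kidney transplant biopsies grouped by histological diagnosis. Antibody-mediated rejection (AMR), in which donor-reactive antibodies injure the graft's microvessels, was the diagnosis of 332 samples. T cell-mediated rejection (TCMR), in which recipient T cells invade tubules and interstitium, was the diagnosis of 437. Both processes were present in 94 mixed samples, and 532 samples showed no rejection and served as controls. The discovery cohort held 1050 samples, 276 with AMR, 342 with TCMR, 76 mixed and 356 without rejection. The validation cohort held 345, 56 with AMR, 95 with TCMR, 18 mixed and 176 without rejection. Median total counts per sample in the discovery cohort were 373405 without rejection, 377541 in AMR, 470595 in TCMR and 641732 in mixed rejection. Median counts of the housekeeping genes (geometric mean) went the other way, 360.4, 332.7, 297.9 and 288.3, so that the median factor that scales a sample to them rose with rejection, 0.934, 1.011, 1.13 and 1.167. The labels do not tie samples to patients, so the p-values treat samples as separate. The comparisons that follow are of the discovery cohort, where diagnosis separated the samples; the validation cohort, read with its labels as deposited, is described after them. Gene values are differences of log2 levels ± SE unless another error is named. Camera p are adjusted over the 25 lists of a comparison, and where 2 values follow each other the first has the preset correlation and the second the estimated correlation.

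The first comparison asked which transcripts distinguish AMR from no rejection. AMR biopsies (n = 276) had higher levels of interferon-gamma-inducible chemokines, NK cell receptors, cytotoxic granule proteins and endothelial transcripts than biopsies without rejection (n = 356). CXCL9, an interferon-gamma-induced chemokine that attracts T and NK cells through CXCR3, was 8.63-fold higher, with a log2 level of 10.12 ± 1.24 (SD) in AMR and 7.01 ± 2.08 without rejection (adjusted p = 3.63e-96). It lay above the no-rejection median in 272 of the 276 AMR samples. GNLY, the granule protein granulysin of NK and T cells, rose by 2.02 ± 0.09 and lay above that median in 265 samples, and the phospholipase PLA1A rose by 1.44 ± 0.05 and did so in 269.

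Of the 27 interferon-gamma response genes, 17 rose in AMR, with a median change of 0.81 (camera p = 1.24e-11, 0.341). Besides CXCL9 (3.11 ± 0.13), the CXCR3 ligands CXCL11 and CXCL10 rose by 2.82 ± 0.12 and 2.11 ± 0.12, and the tryptophan-degrading enzyme IDO1 by 1.94 ± 0.09. MHC class II genes rose as well: 10 of 13 MHC class II genes were higher, with a list median of 0.76 (camera p = 0.000327, 0.516). Among them were HLA-DQA1 (1.52 ± 0.27) and HLA-DQB1 (1.11 ± 0.09). In the MHC class I list 7 of 16 rose, with a list median of 0.58 (camera p = 4.32e-07, 0.341). They included the transactivator NLRC5 (0.91 ± 0.05) and HLA-F (0.88 ± 0.05).

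Of the 24 NK cell genes, 20 were higher with a median change of 0.93 (camera p = 6.47e-08, 0.341). The NK adaptor SH2D1B rose by 1.77 ± 0.07, the T cell receptor delta constant gene TRDC by 1.74 ± 0.09, the activating receptor KLRK1 by 1.29 ± 0.07, the interleukin-2 receptor chain IL2RB by 1.27 ± 0.08 and the NK receptor KLRF1 by 1.10 ± 0.07. All but 1 of the 13 cytotoxic effector genes rose, with a list median of 0.97 (camera p = 0.000221, 0.449). These included NKG7 (1.46 ± 0.09), perforin PRF1 (1.37 ± 0.07) and interferon-gamma itself, IFNG (0.68 ± 0.08). Of the T cell genes 22 of 27 rose, with a list median of 0.83 (camera p = 0.0012, 0.67). Among them were CD8A at 1.16 ± 0.10 and the receptor chain CD247 at 1.12 ± 0.07. In the list of TCMR genes of earlier studies 19 of 31 were higher in AMR too, with a list median of 0.64 (camera p = 0.0374, 0.769). TIGIT rose by 1.04 ± 0.09 and AIM2 by 0.94 ± 0.09. The T helper checkpoint CTLA4 had a change of 0.58 ± 0.09, under the fold minimum, and CXCL13, a B cell chemokine, and the macrophage protease ADAMDEC1 had changes of -0.29 ± 0.16 and -0.04 ± 0.09 with adjusted p of 0.0745 and 0.652.

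Endothelial genes had a median change of 0.42, which was 0.20 above the median of all targets, and 12 of 37 rose (camera p = 4.62e-06, 0.341). The largest were the venular chemokine receptor ACKR1 (1.33 ± 0.10), the cadherin CDH13 (0.86 ± 0.06), von Willebrand factor VWF (0.77 ± 0.09) and the endothelial guidance receptor ROBO4 (0.74 ± 0.03). The list of AMR genes of earlier studies, which draws on the endothelial, NK and interferon groups, had 23 of 36 members higher, with a list median of 0.74. Camera gave an adjusted p of 1.22e-15, and 0.0262 with an estimated correlation. Of the 14 immunoglobulin and plasma cell genes, 9 were higher, with a list median of 0.90 (camera p = 0.972). They included the heavy chain genes IGHG1 (1.34 ± 0.23) and IGHG4 (1.29 ± 0.22), and camera did not separate this list from the other targets.

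Kidney injury genes went the other way: 3 of 32 fell and none rose, with a list median of -0.27 (camera p = 3.75e-08, 0.341). Those that fell were LCN2, the tubular injury marker NGAL, at -1.45 ± 0.16, the acute-phase inhibitor SERPINA3 at -0.999 ± 0.16 and complement C3 at -0.63 ± 0.12. Among 13 neutrophil genes lactoferrin LTF fell, at -0.97 ± 0.17, while S100A9 (-0.48 ± 0.12) and CXCL8 (-0.41 ± 0.10) stayed under the fold minimum. The list's median was -0.13 (camera p = 0.00213, 0.516), and it turned to 0.08 without the members that another list also holds and to 0.0016 with array weights. No tubular epithelium gene of 14 was called. UMOD (0.53 ± 0.14) and SLC12A3 (0.42 ± 0.11) had the largest changes, and the list's median of 0.20 became -0.14 when each sample was re-centred on the median of its targets.

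In all, 172 genes were called between AMR and no rejection, 166 higher and 6 lower, and 594 had an adjusted p under 0.05. The excess of increases depends on the scaling: the median change of all targets was 0.23 as deposited and -0.11 after re-centring on the median of all targets, which left 106 genes, 65 higher and 41 lower. The title-number block, a block for each run of 100 title numbers, was fitted with all 4 groups unless stated and called 222 genes. Counts of list members adjusted over the list alone were identical to the counts over all targets in each of the 25 lists and 7 comparisons (22 of 27 T cell genes in AMR both ways).

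The comparison of TCMR with no rejection asked which transcripts accompany T cell invasion of the graft. TCMR biopsies (n = 342) had higher levels of T cell, cytotoxic, macrophage, B cell and immunoglobulin transcripts than biopsies without rejection (n = 356), while 2 of 37 endothelial and 0 of 14 tubular genes were called. CXCL9 had a log2 level of 10.31 ± 1.55 (SD) against 7.01 ± 2.08, a rise of 3.30 ± 0.12 (adjusted p = 5.03e-116), and lay above the no-rejection median in 337 of 342 samples. CXCL13, the chemokine of lymphoid follicles, had a level of 6.62 ± 1.87 (SD) against 4.05 ± 2.36 and rose by 2.57 ± 0.15, above that median in 321 samples. CD8A, a chain of the cytotoxic T cell coreceptor, rose by 2.54 ± 0.09 and did so in 331 samples.

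All 27 T cell genes rose, with a list median of 1.57 and at least 0.91 (camera p = 6.19e-10, 0.381). CD27 rose by 2.16 ± 0.11, SLAMF6 by 2.002 ± 0.08 and the granzyme GZMK by 1.94 ± 0.09. Of the TCMR genes of earlier studies 30 of 31 rose, with a list median of 1.59 (camera p = 4.45e-10, 0.381). Of the 20 checkpoint genes, 16 rose, with a list median of 1.02 (camera p = 0.000564, 0.385): the inhibitory receptors LAG3 (2.25 ± 0.09), TIGIT (1.85 ± 0.08) and CTLA4 (1.85 ± 0.09), the costimulatory ligand CD80 (2.08 ± 0.15) and IDO1 (2.06 ± 0.09). Of the 13 cytotoxic effector genes, 12 rose, with a list median of 1.63 (camera p = 0.000263, 0.385). These included the chemokine CCL5 at 2.19 ± 0.08, NKG7 at 1.94 ± 0.09, GZMA at 1.69 ± 0.08, IFNG at 1.63 ± 0.08 and GNLY at 1.27 ± 0.08. Of the 24 NK cell genes, 18 rose, with a list median of 0.79 (camera p = 0.0111, 0.552). Among them were IL2RB (1.93 ± 0.08), KLRK1 (1.93 ± 0.07), SH2D1B (0.88 ± 0.06) and KLRF1 (0.61 ± 0.06).

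Of the interferon-gamma response genes 23 of 27 rose, with a list median of 1.14 (camera p = 6.91e-10, 0.381). They included CXCL11 at 2.63 ± 0.11, the guanylate-binding protein GBP5 at 2.33 ± 0.10, CXCL10 at 2.18 ± 0.11 and PLA1A at 0.68 ± 0.05. Of the 30 monocyte and macrophage genes, 26 rose, with a list median of 1.09 (camera p = 0.00119, 0.581). These included the complement components C1QB (1.61 ± 0.09) and C1QA (1.48 ± 0.08), and ADAMDEC1 (1.25 ± 0.08). Of the 16 B cell genes, 14 rose, with a list median of 1.03, with MS4A1, which encodes CD20, at 1.71 ± 0.13 and CD72 at 1.61 ± 0.07. Of the 14 plasma cell and immunoglobulin genes, 12 rose, with a list median of 1.63, with IGHG4 at 1.91 ± 0.21 and IGHM at 1.84 ± 0.18. Camera did not separate either list from the other targets (B cells, camera p = 0.199; plasma cells, camera p = 0.255).

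Antigen presentation genes rose too. All 13 MHC class II genes were higher, with HLA-DQA1 at 1.70 ± 0.25 and a list median of 1.09 (camera p = 9.48e-05, 0.385). In the MHC class I list 14 of 16 genes rose, with the peptide transporter TAP1 at 1.34 ± 0.05 and a list median of 0.90 (camera p = 3.09e-07, 0.381). Of the 16 regulatory and follicular T cell genes, 14 rose, with ICOS at 1.77 ± 0.09 and a list median of 0.998 (camera p = 0.00536, 0.548). Of the 13 neutrophil genes 6 rose, with MMP9 at 0.92 ± 0.11 and FPR1 at 0.76 ± 0.08, and 1 fell, CXCL8 (-0.66 ± 0.09, and 0.28 with the title-number block), with a list median of 0.51 that turned to -0.08 after quantile normalization (camera p = 0.507).

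Endothelial genes had a median change of -0.03, -0.35 from the median of all targets (camera p = 3.31e-06, 0.381). In this list 2 of 37 rose, among them ACKR1 (0.59 ± 0.09, and -0.05 after quantile normalization), while TM4SF1 (-0.54 ± 0.03) and ROBO4 (0.09 ± 0.03) stayed under the fold minimum. The AMR list had 14 of 36 genes higher in TCMR; its median was 0.10 as deposited and turned to -0.37 and -0.32 after re-centring on the median of all targets and quantile normalization (camera p = 0.608). No tubular gene of 14 was called, with a list median of -0.21 (camera p = 0.00145, 0.385). The largest changes were those of TMEM178A, at -0.39 ± 0.05 and UMOD at -0.37 ± 0.13.

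TCMR called 295 genes against no rejection, 288 higher and 7 lower, and 652 had an adjusted p under 0.05. After re-centring on the median of all targets the median change moved from 0.31 to -0.15 and 272 genes were called, 153 higher and 119 lower; with the title-number block 387 were called.

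Mixed rejection was compared with no rejection to ask what the joint diagnosis looks like. Mixed biopsies (n = 76) had higher levels of immunoglobulin, interferon-gamma response, T cell and NK cell transcripts and lower levels of tubular transcripts than biopsies without rejection (n = 356). The immunoglobulin heavy chain gene IGHG1 rose by 4.23 ± 0.36, from a log2 level of 12.05 ± 3.21 (SD) to 16.28 ± 1.43, and lay above the no-rejection median in 74 of 76 samples. CXCL9 rose by 3.89 ± 0.21 to 10.90 ± 0.94 (SD), above that median in 76 of 76 samples, and UMOD, the tubular protein uromodulin, fell by 1.13 ± 0.22, below the median in 62.

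Of the 14 plasma cell and immunoglobulin genes, 13 rose, with a list median of 2.69 (camera p = 0.0243, 0.626). They included IGHG2 (4.13 ± 0.35) beside IGHG1. Of the 16 B cell genes, 14 rose, with a list median of 1.27 (camera p = 0.349). These included CD79A at 2.20 ± 0.18 and MS4A1 at 1.996 ± 0.21. In the interferon-gamma list 26 of 27 rose, with a list median of 1.46 (camera p = 2.35e-09, 0.512). Among them were CXCL11 at 3.52 ± 0.18, GBP5 at 2.88 ± 0.17, CXCL10 at 2.78 ± 0.18 and PLA1A at 1.65 ± 0.08. All 13 MHC class II genes rose, with a list median of 1.42 (camera p = 0.000182, 0.512). They included HLA-DQA1 (2.34 ± 0.42) and HLA-DQB1 (1.72 ± 0.14).

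All 27 T cell genes rose, with a list median of 1.70 (camera p = 3.42e-06, 0.512). These included CD8A at 2.75 ± 0.15 and CD27 at 2.39 ± 0.18, beside CTLA4 (2.10 ± 0.15), CXCL13 (2.74 ± 0.25) and IFNG (1.82 ± 0.13). Of the 24 NK cell genes, 21 rose, with a list median of 1.38 (camera p = 0.00067, 0.512). They included IL2RB at 2.16 ± 0.13, the Fc receptor probe FCGR3A/B at 2.12 ± 0.15, SH2D1B at 1.86 ± 0.11 and KLRF1 at 1.18 ± 0.10. GNLY, of the cytotoxic effector list, rose by 2.18 ± 0.14. Of the 30 monocyte and macrophage genes, 28 rose, with a list median of 1.39 (camera p = 0.00206, 0.626). Among them were CD80 at 2.45 ± 0.25, C1QB at 1.84 ± 0.14 and ADAMDEC1 at 1.54 ± 0.14.

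Of the 14 tubular genes, 9 fell, with a list median of -0.65 (camera p = 4.97e-08, 0.329). They included the fatty acid-binding protein FABP1 (-1.31 ± 0.21), UMOD (-1.13 ± 0.22), the anion exchanger SLC4A1 (-0.93 ± 0.14) and the collecting duct water channel AQP2 (-0.90 ± 0.15). Of the 37 endothelial genes, 10 rose, with ACKR1 at 1.73 ± 0.16, VWF at 0.97 ± 0.14 and ROBO4 at 0.64 ± 0.05, and the list's median of 0.40 turned to -0.23 and -0.21 after re-centring on the median of all targets and quantile normalization (camera p = 0.814). Of the 7 mast cell and eosinophil genes, 4 rose, with the tryptase probe TPSAB1/B2 at 1.34 ± 0.20, the mast cell carboxypeptidase CPA3 at 0.98 ± 0.17 and CCR3 at 0.75 ± 0.11 (-0.09 after quantile normalization), while the IgE receptor chain FCER1A fell (-0.69 ± 0.20). The list's median of 0.62 turned to -0.01 and -0.29 under these scalings (camera p = 0.219). Mixed rejection called 374 genes, 357 higher and 17 lower, with 652 at an adjusted p under 0.05. Re-centring on the median of all targets moved the median change from 0.52 to -0.11 and called 356 genes, 175 higher and 181 lower. The title-number block called 352 genes, and 306 with only the compared groups in the fit. These groups share 1 of the 16 runs, with 17 mixed and 31 no-rejection samples in it. Outside that run the diagnosis and the stretch of the title numbers cannot be told apart in this comparison.

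The values of the lists that follow are given in the order AMR, TCMR and mixed rejection. Of the 16 type I interferon genes, 1, 4 and 5 rose, among them IFI27 in AMR (0.70 ± 0.05) and OASL in TCMR (1.20 ± 0.07) and mixed rejection (1.23 ± 0.12), with list medians of 0.21, 0.32 and 0.37 (camera p = 0.885, 0.875 and 0.706). Of the 9 dendritic cell genes, 1, 3 and 4 rose, with the transcription factor IRF8 at 0.64 ± 0.07, 0.98 ± 0.06 and 1.09 ± 0.10 (camera p = 0.817, 0.645 and 0.985). Of the 25 chemokine genes, 7, 10 and 10 rose and 1, CXCL8, fell in TCMR, though not with the title-number block (0.28). The CXCR3 ligands led the increases, and list medians were 0.20, 0.28 and 0.47 (camera p = 0.578, 0.636 and 0.928). Of the 23 toll-like receptor and inflammasome genes, 2, 6 and 14 rose, with the DNA sensor AIM2 at 0.94 ± 0.09, 1.70 ± 0.08 and 1.995 ± 0.14 and TLR8 at 0.62 ± 0.08, 1.18 ± 0.07 and 1.42 ± 0.12 (camera p = 0.401, 0.877 and 0.786). The medians of the type I interferon, chemokine and toll-like receptor lists turned negative after quantile normalization in all 3 comparisons (-0.24 to -0.01), as did the dendritic cell median in TCMR and mixed rejection (-0.12 and -0.37). Re-centring on the median of all targets turned them negative too, except the toll-like receptor median in mixed rejection and the dendritic cell medians in AMR and TCMR. Of the 18 complement genes, 1, 4 and 6 rose and 1 fell in AMR, and the list lay below the median of all targets in each comparison, by -0.21, -0.14 and -0.16 (camera p = 0.0698, 0.194 and 0.219). Its medians of 0.01, 0.17 and 0.35 turned negative after re-centring (-0.325, -0.288 and -0.275) and quantile normalization (-0.156, -0.326 and -0.238), and in TCMR without the members that another list also holds (-0.07). C1QB rose in each (0.60 ± 0.09, 1.61 ± 0.09 and 1.84 ± 0.14), while C3 fell in AMR and rose in TCMR (0.67 ± 0.11) and mixed rejection (1.02 ± 0.18). Of the 24 fibrosis genes 2 rose in TCMR and 5 in mixed rejection, and the list lay below the median of all targets in both, by -0.27 and -0.41 (camera p = 0.00288 and 0.0112, and 0.418 and 0.525 with an estimated correlation). Its medians of 0.04 and 0.11 turned to -0.42 and -0.52 after re-centring. None of the 8 podocyte and glomerular genes was called, with COL4A5 at -0.37 ± 0.04 in TCMR and VEGFA at -0.43 ± 0.07 in mixed rejection, and the list medians of -0.21 and -0.25 had camera p of 0.00145 and 0.000291, and 0.381 and 0.349 with an estimated correlation.

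**Figure D1:**
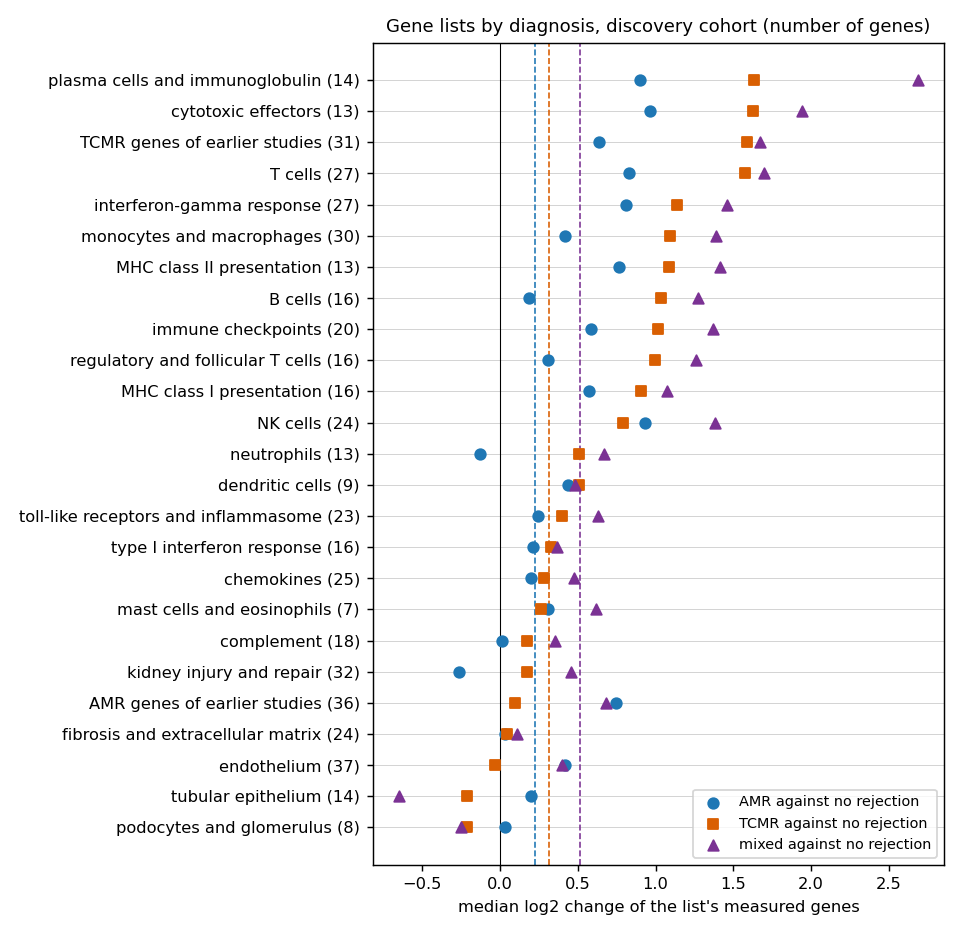
Median log2 change against no rejection of each of the 25 gene lists in AMR (circles), TCMR (squares) and mixed rejection (triangles), discovery cohort; the number of measured genes is in parentheses and dashed lines mark the median of all 758 targets in each comparison (0.23, 0.31 and 0.52). The T cell, B cell, plasma cell, cytotoxic and macrophage lists lie to the right of the dashed lines in TCMR and mixed rejection, while the endothelial list lies at 0.42 in AMR and -0.03 in TCMR, and its mixed rejection value of 0.40 turns negative after re-centring or quantile normalization.

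AMR was compared directly with TCMR to ask what tells the rejection types apart. AMR biopsies (n = 276) had higher levels of endothelial and NK adaptor transcripts, and TCMR biopsies (n = 342) had higher levels of T cell, B cell and macrophage transcripts. VWF was higher in AMR by 0.81 ± 0.09, with 204 of 276 AMR samples above the TCMR median, and the G protein subunit GNG11 by 0.81 ± 0.03, with 273 above it. CXCL13 was lower in AMR by 2.86 on the log2 scale (-2.86 ± 0.16), with 263 AMR samples below the TCMR median, and LAG3 was lower (-1.66 ± 0.10), with 271 below it.

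Of the 37 endothelial genes 15 were higher in AMR and 1 was lower. The list's median was 0.53, and camera gave an adjusted p of 1.80e-25, or 0.00207 with an estimated correlation. TM4SF1 (0.80 ± 0.04) and CDH13 (0.78 ± 0.06) followed VWF and GNG11. The AMR list had 15 of 36 genes higher in AMR, with a list median of 0.52, including SH2D1B (0.89 ± 0.07) and the fractalkine receptor CX3CR1 of cytotoxic lymphocytes and monocytes (0.88 ± 0.07), with an adjusted p of 4.53e-15, or 0.0184 with an estimated correlation. Of the 24 NK cell genes, 2 were higher in AMR, IL2RB (-0.66 ± 0.09) and KLRK1 (-0.64 ± 0.07) were lower, and the median of 0.06 turned to -0.06 without the members that another list also holds and to -0.11 with the title-number block (camera p = 0.166).

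Of the 31 TCMR genes of earlier studies, 26 were lower in AMR, with a list median of -0.86 (camera p = 1.03e-10, 0.674). These included CXCR6, a receptor of tissue-resident T cells, at -1.39 ± 0.09 and CD8A at -1.38 ± 0.10. Of the 27 T cell genes, 21 were lower, with a list median of -0.82 (camera p = 1.07e-07, 0.674). Among them were the costimulator ICOS (-1.32 ± 0.09) and CD27 (-1.30 ± 0.11). Of the 16 regulatory and follicular T cell genes, 9 were lower, with a list median of -0.68 (camera p = 0.000791, 0.674). They included CTLA4 at -1.26 ± 0.09 and the interleukin-2 receptor IL2RA at -0.86 ± 0.08. Of the 16 B cell genes, 12 were lower, with a list median of -0.80 (camera p = 0.00386, 0.678). These included MS4A1 at -1.36 ± 0.14 and CD72 at -0.93 ± 0.08. Of the 30 monocyte and macrophage genes, 14 were lower, with a list median of -0.52 (camera p = 0.000376, 0.737). Among them were the chemokine CCL18 at -1.63 ± 0.14, ADAMDEC1 at -1.29 ± 0.09, and the scavenger receptor CD163 at -1.15 ± 0.10.

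Of the 32 kidney injury genes, 8 were lower in AMR, with a list median of -0.29 (camera p = 0.122). They included LCN2 (-1.38 ± 0.16), C3 (-1.31 ± 0.12) and SERPINA3 (-1.26 ± 0.16). Of the 18 complement genes, 5 were lower, with C1QB at -1.01 ± 0.09 and factor B, CFB, at -0.71 ± 0.07; their median of -0.08 turned to 0.05 and 0.07 after re-centring on the median of all targets and quantile normalization (camera p = 0.923). Of the 14 tubular genes, 3 were higher in AMR, UMOD (0.90 ± 0.14), ASB15 (0.65 ± 0.10) and FABP1 (0.63 ± 0.13), with a median of 0.43 (camera p = 0.00788, 0.678). Of the fibrosis genes collagens COL1A1 (-1.04 ± 0.12) and COL3A1 (-0.63 ± 0.09) and the metalloproteinase MMP9 (-0.76 ± 0.12) were lower and caveolin CAV1 (0.61 ± 0.05) was higher, and the median of -0.05 turned positive, 0.07 and 0.08, under the same scalings (camera p = 0.115). FCER1A was higher in AMR by 1.41 ± 0.13, the 1 called gene of the 7 mast cell and eosinophil genes. KIT (0.29 ± 0.04) and CCR3 (-0.28 ± 0.07) were not called, and the median of 0.06 turned negative with the title-number block (camera p = 0.214).

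Between AMR and TCMR 158 genes were called, 33 higher and 125 lower in AMR, and 618 had an adjusted p under 0.05. Re-centring on the median of all targets called 144, 57 higher and 87 lower, and quantile normalization called 140, 64 higher and 76 lower. With all samples and cohort as a covariate 92 genes were called, and with the title-number block 308, 59 higher and 249 lower. With only AMR and TCMR in the fit the block called 178 genes, where other splits of the labels within runs reached up to 135. AMR and TCMR samples share 1 of the 16 runs, with 10 AMR and 23 TCMR samples in it. Outside that run the diagnosis and the stretch of the title numbers cannot be told apart in this comparison.

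The increases of AMR and TCMR overlapped. Of the 166 genes higher in AMR and the 288 higher in TCMR, 146 were higher in both, where independent lists share 63.1. With 178 separate controls for each comparison 166 were higher in both. The simulated unchanged groups called at most 1 and 0 genes higher, so they cannot gauge this overlap, which was not counted after re-centring. The changes correlated across the 758 genes, which are not independent replicates, with Pearson's r of 0.72 and Spearman's rho of 0.69. Shared controls alone gave r between -0.26 and 0.92 in the simulations, so r is uninformative here, while their covariance was at most 0.0172 against 0.207 observed and 0.218 with separate controls. A single gene was lower in both, where independent lists share 0.0554 and the simulated unchanged groups reached 1 at most, and 2 genes were called in opposite directions.

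**Figure D2:**
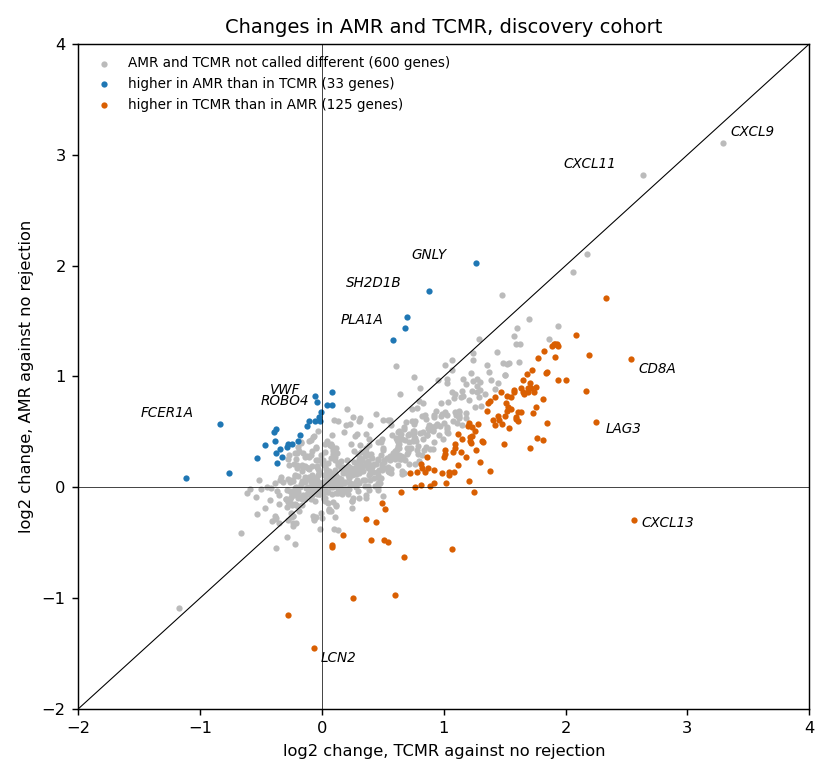
Each point is 1 of 758 target genes; the x axis gives its log2 change in TCMR and the y axis its log2 change in AMR, both against no rejection in the discovery cohort, with the line of equality. Blue and orange points are the 33 genes called higher in AMR than in TCMR and the 125 called higher in TCMR: GNLY, SH2D1B, PLA1A, VWF and ROBO4 lie above the line and CXCL13, LAG3, CD8A and LCN2 below it.

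Mixed rejection was set against each pure diagnosis to ask what the second process adds. Against AMR (n = 276), mixed biopsies (n = 76) had higher immunoglobulin, B cell and TCMR-associated transcripts and lower tubular transcripts. CXCL13 was higher by 3.04 ± 0.25, above the AMR median in 73 of 76 samples, IGHG1 by 2.89 ± 0.37, in 73, and LCN2 by 1.47 ± 0.26, in 62. UMOD was lower (-1.66 ± 0.23), below the AMR median in 68. Of the 14 plasma cell genes, 13 were higher, with a list median of 1.72 (camera p = 0.00123, 0.638). These included IGHG2 at 2.85 ± 0.36 and IGHG4 at 2.83 ± 0.35. Of the 31 TCMR genes, 29 were higher, with a list median of 1.04 (camera p = 3.13e-08, 0.638). Among them were LAG3 at 1.63 ± 0.16, CD8A at 1.59 ± 0.15 and ADAMDEC1 at 1.59 ± 0.14. Of the 16 B cell genes, 14 were higher, with a list median of 1.01 (camera p = 0.00575, 0.638). They included CD79A at 1.74 ± 0.18 and MS4A1 at 1.65 ± 0.22. Of the 14 tubular genes, 10 were lower, with a list median of -0.87 (camera p = 4.38e-11, 0.0712). These included FABP1 at -1.70 ± 0.21, AQP2 at -1.30 ± 0.15 and ASB15 at -1.17 ± 0.16. Of the 32 injury genes, 13 were higher, with a list median of 0.53, including C3 (1.65 ± 0.19), SERPINA3 (1.57 ± 0.25) and NNMT (1.15 ± 0.18) (camera p = 0.105). Of the 13 neutrophil genes, 10 were higher, with a list median of 0.70, including LTF (1.81 ± 0.28), S100A9 (1.14 ± 0.19), the formyl peptide receptor FPR1 (1.08 ± 0.15) and S100A8 (1.03 ± 0.19) (camera p = 0.158). The comparison called 260 genes, 237 higher and 23 lower, and 172 genes, 108 higher and 64 lower, after re-centring on the median of all targets, which moved the median change from 0.31 to 0.02; with the title-number block 166 were called.

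Against TCMR (n = 342), mixed biopsies (n = 76) differed in immunoglobulin, endothelial, NK and tubular genes, and T cell genes were not called. IGHG1 was higher by 2.36 ± 0.36, above the TCMR median in 67 of 76 samples, ACKR1 by 1.14 ± 0.16, in 65, and PLA1A by 0.96 ± 0.08, in 72. Of the 14 plasma cell genes, 10 were higher, with a list median of 1.22 (camera p = 0.00257, 0.921). Among them were IGHG2 at 2.24 ± 0.35 and IGHG4 at 2.21 ± 0.35. Of the 37 endothelial genes, 6 were higher, with a list median of 0.43, with VWF at 1.01 ± 0.14, CDH13 at 0.82 ± 0.10 and CAV1 at 0.73 ± 0.08, and 12 of 36 AMR genes were higher, with a list median of 0.51. Camera gave adjusted p of 4.49e-22 and 7.85e-20, and 0.00335 for both with an estimated correlation. Of the 24 NK cell genes, 6 were higher, with a list median of 0.41 (camera p = 0.00425, 0.921). They included SH2D1B at 0.98 ± 0.11, FGFBP2 at 0.88 ± 0.14, FCGR3A/B at 0.74 ± 0.15 and an inhibitory KIR probe (KIR_Inhibiting_Subgroup_2) at 0.66 ± 0.12. Of the 14 tubular genes, 5 were lower, with a list median of -0.43, with FABP1 at -1.07 ± 0.21, UMOD at -0.76 ± 0.22, AQP2 at -0.73 ± 0.15 and the sodium-chloride cotransporter SLC12A3 at -0.60 ± 0.18. Camera gave an adjusted p of 6.97e-12, and 0.0205 with an estimated correlation. None of the 27 T cell genes was called, with CD27 at 0.23 ± 0.18, CD8A at 0.21 ± 0.15, CCR7 at 0.19 ± 0.12 and SH2D1A at 0.19 ± 0.13, and their median of 0.09 turned to -0.07 and -0.10 after re-centring on the median of all targets and quantile normalization (camera p = 0.112). The comparison called 48 genes, 43 higher and 5 lower. Re-centring on the median of all targets called 34, 19 higher and 15 lower, and quantile normalization called 40, 23 higher and 17 lower. With the title-number block and all 4 groups in the fit it called 115 genes, 22 higher and 93 lower, of which 12 were among the 48. In that fit the plasma cell, tubular and T cell medians turned to -0.09, 0.33 and -0.86. With only the compared groups in the fit the block called 2 genes, where other splits of the labels within runs reached up to 7. The groups share a single run with 17 mixed and 4 TCMR samples, so the diagnosis and the stretch of the title numbers cannot be told apart in this comparison.

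The departure of mixed rejection from the sum of the AMR and TCMR changes asked whether the processes add on the log2 scale. Interferon-gamma response genes rose less in mixed rejection than the sum: 12 of 27 were called lower, with a list median of -0.50 (camera p = 8.24e-10, 0.509). These included CXCL9 at -2.51 ± 0.25, CXCL11 at -1.93 ± 0.22, CXCL10 at -1.51 ± 0.22 and IDO1 at -1.34 ± 0.18. Of the 27 T cell genes, 19 did so, with a list median of -0.70 (camera p = 4.07e-07, 0.509). Among them were CD247 (-0.97 ± 0.13) and CD8A (-0.95 ± 0.18). Of the 14 tubular genes, 8 lay below the sum, with a list median of -0.65 (camera p = 0.0011, 0.509). They included FABP1 at -1.45 ± 0.25, UMOD at -1.28 ± 0.26, AQP2 at -1.13 ± 0.17 and SLC12A3 at -1.02 ± 0.21. Above the sum lay 10 of 32 injury genes, with LCN2 at 1.54 ± 0.31, SERPINA3 at 1.31 ± 0.29 and C3 at 0.98 ± 0.22, with a list median of 0.40 (camera p = 1.17e-09, 0.509). So did 5 of 14 plasma cell genes, with IGHG1 at 1.03 ± 0.43 and IGHG3 at 0.98 ± 0.41, with a list median of 0.55 (camera p = 0.0113, 0.611). Of 100 splits, the real one included, 5 gave a plasma cell median as far from that of all targets, so chance cannot be excluded for that list. Of 115 called genes 20 lay above and 95 below the sum. Re-centring on the median of all targets gave 47 above and 46 below, all samples with cohort as a covariate gave 39 genes, and the title-number block gave 265 genes and turned the injury and plasma cell medians to -0.03 and -1.12.

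List scores per sample showed how far the groups overlapped. In the discovery cohort the endothelial score separated AMR from TCMR with an AUC of 0.9, the AMR list score with 0.858, the TCMR list score with 0.162 and the T cell score with 0.183, where 0.5 is no separation and values under it mean lower scores in AMR. Against no rejection the AMR list score reached an AUC of 0.933 and the NK score 0.867 in AMR, and the MHC class I, interferon-gamma, checkpoint and T cell scores reached 0.890, 0.872, 0.867 and 0.866 in TCMR. Of the 25 lists 24 separated AMR from TCMR, 21 AMR from no rejection and 22 TCMR from no rejection at an adjusted p under 0.05 (permutation test, two-sided, 25 lists in 3 pairs adjusted together; the lowest p of 1e-05 is the smallest that 100000 permutations can give).

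In the validation cohort, read with its labels as deposited, limma called none of these differences. CXCL9 had a change of 0.10 ± 0.36 in AMR (n = 56 against 176), -0.52 ± 0.30 in TCMR (n = 95) and 0.39 ± 0.58 in mixed rejection (n = 18), and the intervals of the AMR change, -0.61 to 0.80, and the TCMR change, -1.10 to 0.07, exclude the discovery values. GNLY had changes of -0.13 ± 0.21, -0.32 ± 0.18 and 0.13 ± 0.34, and ROBO4 a change of 0.01 ± 0.08 in AMR. The limma fit called 0 genes in each of the 7 comparisons, with 6, 12, 13, 4, 4, 23 and 14 genes at an unadjusted p under 0.05 and lowest adjusted p between 0.828 and 0.999. The genes called in discovery kept their sign in 34 of 172 genes in AMR, 25 of 295 in TCMR and 289 of 374 in mixed rejection, and the changes of the cohorts correlated across genes with r of -0.18, -0.74 and 0.41 (rho -0.27, -0.70 and 0.38). Signs were kept in 68 of 158 genes between AMR and TCMR (r 0.07, rho -0.02), in 227 of 260 between mixed rejection and AMR (r 0.54, rho 0.53), in 42 of 48 between mixed rejection and TCMR (r 0.43, rho 0.43) and in 22 of 115 for the departure from the sum (r -0.30, rho -0.34). The change itself differed between cohorts by at least 1.5-fold in 196, 300 and 339 genes in AMR, TCMR and mixed rejection against no rejection, in 147 between AMR and TCMR, 60 between mixed and AMR, 0 between mixed and TCMR, and 130 for the departure from the sum. None of the 25 list scores separated the groups at an adjusted p under 0.05 in any of 3 pairs, with AUC between 0.436 and 0.574. All these values hold for the labels as deposited, which may be out of register with the values, as weighed further below. They therefore cannot be read as a failure of the discovery differences to recur.

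**Figure D3:**
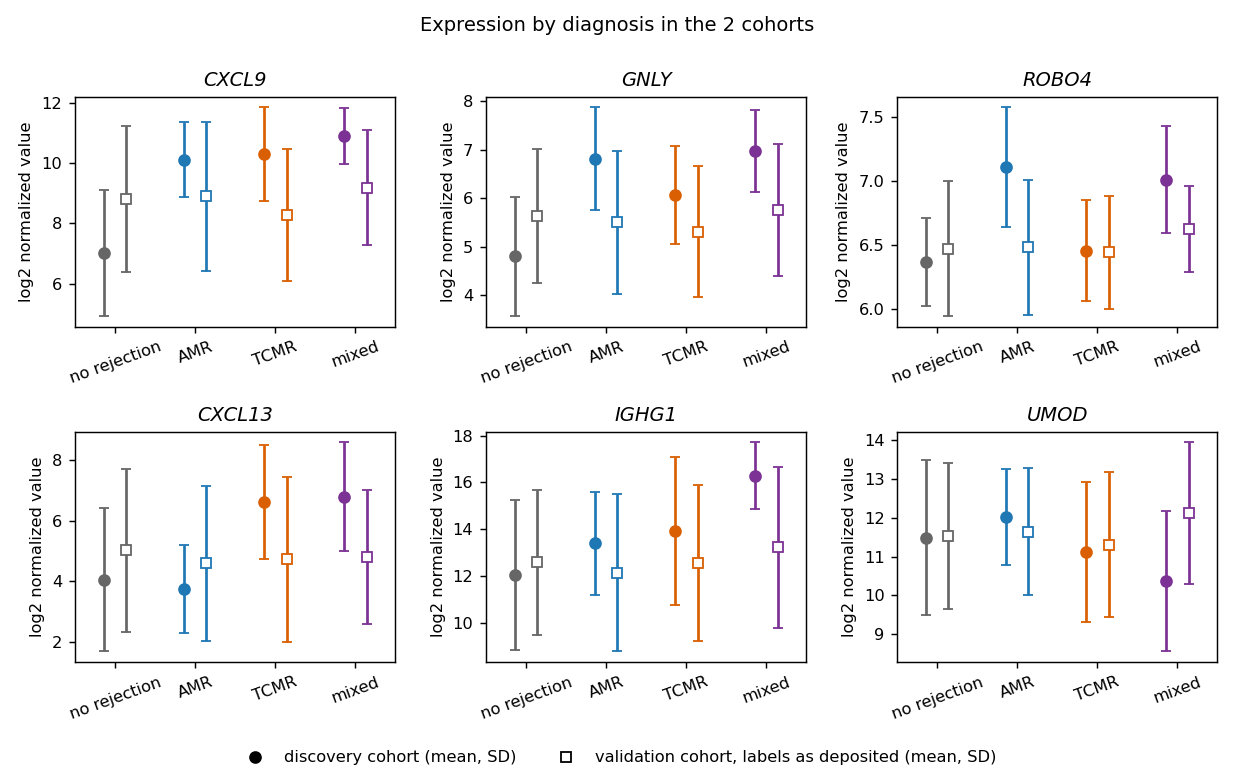
Mean log2 normalized level and SD of 6 genes by diagnosis; filled circles are the discovery cohort (356 no rejection, 276 AMR, 342 TCMR and 76 mixed samples) and open squares the validation cohort with labels as deposited (176, 56, 95 and 18). In the discovery cohort CXCL9 is near 7.01 without rejection and 10.12 to 10.90 in rejection, whereas the validation groups lie close together.

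A classifier gave the same contrast. In 10-fold cross-validation within the discovery cohort it assigned 874 of 1050 samples (83.2%, Wilson 95% interval 80.9 to 85.4) their own diagnosis: 88.2% without rejection, 80.8% in AMR, 82.2% in TCMR and 73.7% in mixed rejection. The model held 114 genes, and coefficients that were largest for a class were ROBO4 and FCER1A for AMR, the inverse of GNG11 for TCMR, IGHG2 and PLA1A for mixed rejection and the inverse of KLRK1 for no rejection. In the validation cohort 112 of 345 samples (32.5%, 27.7 to 37.6) received their own label, 47.2% without rejection, 12.5% in AMR, 18.9% in TCMR and 22.2% in mixed rejection. Balanced over classes this was 25.2%, and 36 of 100 trainings on permuted labels did as well (median 24.3%). The model did not find the validation samples alike: it assigned 174 to no rejection, 51 to AMR, 80 to TCMR and 40 to mixed rejection.

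**Figure D4:**
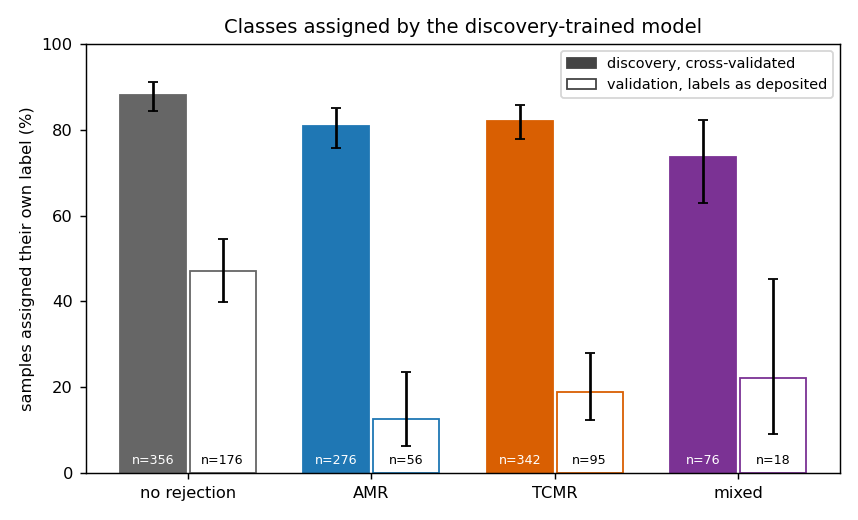
Percent of samples of each diagnosis that the discovery-trained model assigned their own label, with Wilson 95% intervals and group sizes; filled bars are from cross-validation in the discovery cohort and open bars are the validation cohort with labels as deposited. Discovery bars lie between 73.7 and 88.2% and validation bars between 12.5 and 47.2%.

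The viral probes separated a few samples. Each probe for BK polyomavirus, a virus that infects tubular cells of transplants, exceeded its threshold, the level above which 5% of the no-rejection samples lay, in 18 of 356 samples without rejection, 13 of them for both probes, and in 0 of 276 AMR, 0 of 342 TCMR and 0 of 76 mixed samples (Fisher's exact test, two-sided, p = 3.31e-05, 6.49e-06 and 0.0529 for each probe). The no-rejection count was set by the threshold, so only the rejection counts carry information, and VP1 levels in some rejection samples lay just under the threshold. The exact intervals allow shares of up to 1.33, 1.07 and 4.74%. Below that range the large T probe was lower in rejection, with medians of 2.18, 2.03 and 1.07 against 3.33 log2, while the VP1 capsid probe was higher, with 4.18, 4.77 and 4.39 against 3.25. The cytomegalovirus probe UL83 exceeded its threshold in 11.6% of AMR, 12.9% of TCMR and 18.4% of mixed samples (p = 0.00288, 0.000293 and 0.000293), and the Epstein-Barr virus probe LMP2 in 6.16, 11.1 and 6.58% (p = 0.601, 0.00337 and 0.576), at log2 thresholds of 3.26 and 2.67 that correspond to few counts. UL83 medians were 2.53, 2.65 and 2.60 against 2.37 log2 without rejection. The mean log2 scaling factor was higher in these groups too, at 0.10, 0.21 and 0.25 against -0.09. At so few counts the shares cannot tell viral transcripts from background counts raised with the scaling. The 12 housekeeping genes, to which the samples were scaled, changed by between -0.22 and 0.25 in the 6 pairwise comparisons, and none reached 1.5-fold.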

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

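The 3 tests of the validation cohort in this part (of its labels, its variation and its depth) and the counts over random splits were chosen after the results were seen. A difference between the cohorts was tested by a cohort-by-diagnosis term in limma, and it reached 1.5-fold at an adjusted p under 0.05 in 196 genes for AMR against no rejection, 300 for TCMR against no rejection and 339 for mixed rejection against no rejection. It did so in 147 genes for AMR against TCMR, in 60 for mixed rejection against AMR and in 130 for the departure from the sum. When cohort labels were shuffled within each diagnosis, 1 of 100 splits, the real one, gave as many genes in each of these 6 comparisons. The highest other counts were 0, 1, 3, 24, 11 and 5, so chance can be excluded for them. Mixed rejection against TCMR gave 0 genes, a count that 100 of 100 splits reach in any event (highest other 7), so the splits decide nothing there. Within the discovery cohort, mixed rejection departed from the sum of the AMR and TCMR changes in 115 genes by a test of the difference itself, and 1 of 100 splits gave as many (highest other 29).

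The pattern weighed for these cohort differences is that no gene changed by diagnosis in the validation cohort with its labels as deposited. The tables argue against lower depth there, with a ratio of median total counts of 1.004. In this cohort the spread of the 392 genes called against no rejection was 1.07 times that expected from the discovery groups (bootstrap interval 1.04 to 1.11, and 0.887 with no group differences). Their total spread was thus not smaller. It holds variation of every source, so it cannot tell whether the rejection-related part was smaller. A candidate explanation is that values and labels of this cohort are out of register: with the labels put in alphabetical order of the codes in the sample titles, the class that the discovery-trained model assigned equalled the label in 76.8% of samples, against 32.5% as deposited, 30.4% in numerical order and at most 40.6% in 100 random orders (median 35.5%). In the discovery cohort the deposited order gave 83.2% and the alphabetical order 30.6%. This is a hypothesis found and tested on the same samples after 3 orders were tried, and no sample was moved to another group in any comparison. The agreement of 76.8% goes against an absence of these changes in the cohort as the whole cause, while other biological differences between the cohorts were not tested.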

How the results depend on the processing

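Chosen after the data were seen were the title-number block, the scaling factor as a covariate, the fit without the 5% of samples with the largest scaling factor and the cross-validation within discovery. Numbers in parentheses are the values under the alternative, and the order of counts is AMR, TCMR and mixed rejection against no rejection, AMR against TCMR, mixed rejection against AMR and TCMR, and the departure from the sum. Counts of called genes stayed within 1.5 times the reported count in every comparison fitted under array weights (53 to 378 genes), the scaling factor as a covariate (47 to 342), the fit without the 5% of samples with the largest scaling factor (48 to 374), the fit of only the compared groups (49 to 373) and the Wilcoxon rank-sum test (49 to 374), the last pair not run for the departure from the sum. Fits without a trend and with robust variances called identical numbers. Of the results other than counts, 3611 kept their direction and side of the threshold over all alternatives, 316 kept their direction and lost the call, 36 kept it and gained the call, and 241 reversed. The 3611 include 224 gene and 88 list results of re-centring on the housekeeping genes, which moved nothing. They also include 224 gene results each of the fits without a trend and with robust variances, so the tally overstates how far the results were tried. The genes higher in both AMR and TCMR numbered 166 with separate controls. With the median of members, the lists whose scores separated the groups in discovery numbered 20 for AMR and 23 for TCMR against no rejection and 23 for AMR against TCMR. In validation they numbered 0 in each pair.

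The cause was not tested for the changes that follow, except that a fold minimum of 2 or none, fewer genes or fewer list members change counts by construction. A fold minimum of 2 left 53, 171, 235, 27, 80, 11 and 24 genes, and without a fold minimum 594, 652, 652, 618, 602, 385 and 381 were called. With both cohorts and cohort as a covariate 89 genes were called in AMR, 92 in AMR against TCMR and 39 for the departure, where 9 lists were called. Re-centring on the median of all targets called 106 genes in AMR and 172 in mixed rejection against AMR, and quantile normalization called 91 in AMR. Without the lowest 25% of genes 247 were called in mixed rejection. With all 4 groups in the fit the title-number block called 308 genes in AMR against TCMR, 166 and 115 in mixed rejection against AMR and TCMR and 265 for the departure, and 9 lists in mixed rejection against TCMR. Camera with an estimated correlation called 1, 0, 0, 2, 0, 3 and 0 lists, and without shared members 7 lists were called in AMR against TCMR and 3 in mixed rejection against TCMR. Cross-validation in discovery gave 83.2% of samples their own label, against 31.01 to 35.4% of validation samples under the other classifier settings.

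Re-centring and quantile normalization turned the sign of 44 list medians, for which the cause was not tested beyond the shift of the median of all targets. After re-centring on the median of all targets the changes were these. The chemokine (-0.14), complement (-0.32), toll-like receptor (-0.098), tubular (-0.14) and type I interferon (-0.13) medians turned in AMR against no rejection. The AMR gene (-0.37), chemokine (-0.18), complement (-0.29), fibrosis (-0.42), toll-like receptor (-0.060) and type I interferon (-0.14) medians turned in TCMR against no rejection. The chemokine (-0.15), complement (-0.28), dendritic cell (-0.15), endothelial (-0.23), fibrosis (-0.52), mast cell (-0.0081) and type I interferon (-0.26) medians turned in mixed rejection against no rejection. The complement (0.046) and fibrosis (0.069) medians turned in AMR against TCMR. The T cell (-0.073) median turned in mixed rejection against TCMR. ROBO4 (-0.38) reversed in TCMR against no rejection. After quantile normalization they were these. The chemokine (-0.017), complement (-0.16), toll-like receptor (-0.13) and type I interferon (-0.010) medians turned in AMR against no rejection. The AMR gene (-0.32), chemokine (-0.19), complement (-0.33), dendritic cell (-0.12), fibrosis (-0.23), neutrophil (-0.077), toll-like receptor (-0.19) and type I interferon (-0.047) medians turned in TCMR against no rejection. The chemokine (-0.24), complement (-0.24), dendritic cell (-0.37), endothelial (-0.21), fibrosis (-0.34), mast cell (-0.29), toll-like receptor (-0.057) and type I interferon (-0.17) medians turned in mixed rejection against no rejection. The complement (0.074) and fibrosis (0.078) medians turned in AMR against TCMR. The T cell (-0.097) median turned in mixed rejection against TCMR. ACKR1 (-0.049) and ROBO4 (-0.37) reversed in TCMR against no rejection. CCR3 (-0.093) reversed in mixed rejection against no rejection. CCR7 (-0.047) and SH2D1A (-0.029) reversed in mixed rejection against TCMR. With array weights the neutrophil (0.0016) median in AMR against no rejection, the fibrosis (-0.043) median in TCMR against no rejection, the T cell (-0.0046) median in mixed rejection against TCMR and ADAMDEC1 (0.11) in AMR against no rejection turned. Without shared members the neutrophil (0.078) median turned in AMR against no rejection. The complement (-0.072) and fibrosis (-0.016) medians did so in TCMR against no rejection, and the NK cell (-0.057) and complement (0.046) medians in AMR against TCMR.

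With the title-number block, of whose 16 runs the groups of a pair share 1 to 8, 9 list medians and 14 named genes reversed, and the cause was not tested. The endothelial (0.029) median turned in TCMR against no rejection. The fibrosis (-0.034) median turned in mixed rejection against no rejection. The NK cell (-0.11) and mast cell (-0.33) medians turned in AMR against TCMR. The T cell (-0.86), plasma cell (-0.088) and tubular (0.33) medians turned in mixed rejection against TCMR. The kidney injury (-0.032) and plasma cell (-1.12) medians turned in the departure from the sum. CXCL8 (0.28) reversed in TCMR against no rejection. ACKR1 (-0.082), CCR7 (-0.36), CD27 (-1.29), CD8A (-0.68), FABP1 (0.51), IGHG2 (-0.069), IGHG4 (-0.062), SH2D1A (-0.51), SLC12A3 (0.94) and UMOD (0.12) reversed in mixed rejection against TCMR. C3 (-0.085), IGHG1 (-1.08) and IGHG3 (-1.16) reversed in the departure from the sum.

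In the validation cohort alone limma called 0 genes in each of the 7 comparisons, with 6, 12, 13, 4, 4, 23 and 14 at an unadjusted p under 0.05. Camera called 6, 11, 9, 6, 8, 11 and 11 lists in the same order. In this cohort 46 list medians and 113 named genes reversed, and the cause was not tested beyond the weighing of the labels. The AMR gene (-0.0020), MHC class I (-0.055), MHC class II (-0.085), NK cell (-0.035), T cell (-0.14), TCMR gene (-0.12), chemokine (-0.034) and complement (-0.069) medians turned in AMR against no rejection. The cytotoxic (-0.076), dendritic cell (-0.040), endothelial (-0.0017), interferon-gamma (-0.031), plasma cell (-0.24), toll-like receptor (-0.042) and type I interferon (-0.017) medians did so there too. The AMR gene (-0.044), B cell (-0.10), MHC class I (-0.13), MHC class II (-0.18), NK cell (-0.086), T cell (-0.21) and TCMR gene (-0.20) medians turned in TCMR against no rejection. The chemokine (-0.018), complement (-0.024), cytotoxic (-0.21), dendritic cell (-0.019), checkpoint (-0.092), interferon-gamma (-0.16) and macrophage (-0.15) medians did so there too. The plasma cell (-0.083), podocyte (0.13), regulatory and follicular T cell (-0.11), toll-like receptor (-0.0095), tubular (0.088) and type I interferon (-0.10) medians did so there too. The B cell (-0.13) and fibrosis (-0.045) medians turned in mixed rejection against no rejection. The B cell (0.025), T cell (0.069), TCMR gene (0.066), mast cell (-0.14), macrophage (0.021) and regulatory and follicular T cell (0.025) medians turned in AMR against TCMR. The B cell (-0.068) median turned in mixed rejection against AMR. The T cell (0.38) and interferon-gamma (0.39) medians turned in the departure from the sum. ACKR1 (-0.17), AIM2 (-0.12), C1QB (-0.16), CD247 (-0.14), CD8A (-0.17), CDH13 (-0.036), CTLA4 (-0.050), CXCL10 (-0.019) and CXCL11 (-0.026) reversed in AMR against no rejection. GNLY (-0.13), HLA-DQA1 (-1.30), HLA-F (-0.032), IDO1 (-0.13), IFI27 (-0.0062), IFNG (-0.11), IGHG1 (-0.46), IGHG4 (-0.49) and IL2RB (-0.24) did so too. IRF8 (-0.11), KLRK1 (-0.14), NKG7 (-0.085), NLRC5 (-0.047), PRF1 (-0.023), TIGIT (-0.25), TLR8 (-0.11), TRDC (-0.17) and VWF (-0.12) did so too. ACKR1 (-0.19), ADAMDEC1 (-0.063), AIM2 (-0.22), C1QA (-0.20), C1QB (-0.21), C3 (-0.024), CCL5 (-0.21), CD27 (-0.35), CD72 (-0.21), CD80 (-0.23), CD8A (-0.21) and COL4A5 (0.13) reversed in TCMR against no rejection. CTLA4 (-0.30), CXCL10 (-0.39), CXCL11 (-0.48), CXCL13 (-0.30), CXCL8 (0.10), CXCL9 (-0.52), FPR1 (-0.069), GBP5 (-0.33), GNLY (-0.32), GZMA (-0.19), GZMK (-0.26) and HLA-DQA1 (-0.47) reversed in TCMR against no rejection. ICOS (-0.26), IDO1 (-0.38), IFNG (-0.28), IGHG4 (-0.16), IGHM (-0.13), IL2RB (-0.32), IRF8 (-0.17), KLRF1 (-0.22), KLRK1 (-0.28), LAG3 (-0.29), MS4A1 (-0.12) and NKG7 (-0.15) reversed in TCMR against no rejection. OASL (-0.10), PLA1A (-0.12), ROBO4 (-0.030), SH2D1B (-0.036), SLAMF6 (-0.33), TAP1 (-0.19), TIGIT (-0.26), TLR8 (-0.12) and TMEM178A (0.067) did so too. AQP2 (0.29), CCR3 (-0.049), CXCL13 (-0.22), MS4A1 (-0.42), SLC4A1 (0.084), TPSAB1/B2 (-0.056), UMOD (0.59) and VEGFA (0.019) reversed in mixed rejection against no rejection. ASB15 (-0.14), C1QB (0.056), CAV1 (-0.017), CD27 (0.12), CD72 (0.20), CD8A (0.044), CDH13 (-0.084), CTLA4 (0.25) and CXCR6 (0.13) reversed in AMR against TCMR. FCER1A (-0.12), GNG11 (-0.0021), ICOS (0.066), IL2RB (0.074), KIT (-0.093), KLRK1 (0.14), LAG3 (0.18), MS4A1 (0.10) and VWF (-0.16) did so too. AQP2 (0.11), MS4A1 (-0.40), SERPINA3 (-0.23) and UMOD (0.48) reversed in mixed rejection against AMR. AQP2 (0.22) and UMOD (0.81) reversed in mixed rejection against TCMR. AQP2 (0.033), CD247 (0.34), CD8A (0.66), CXCL10 (0.92), CXCL11 (1.15), CXCL9 (0.81), IDO1 (0.74), SERPINA3 (-0.35) and UMOD (0.71) reversed in the departure from the sum.

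Some of the alternatives chosen before the data were examined were not run or were void. A pseudocount of 10 and a DESeq2 fit had been set for tables of linear values or raw counts, and they were not run on the counts recovered from this log2 table. The mean of the housekeeping genes is constant over samples, so re-centring on it moved nothing and neither the removal of samples with a low mean nor its use as a covariate could be run, and there were no near-identical pairs to remove. Depth limits the low-count genes: 140 of 758 targets had a median under 20 counts over all samples, where a single molecule moves the log2 level.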

Other observations

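Chosen after the results were seen were the fit with the scaling factor as a covariate, the counts over random splits and the test of the BK probes in runs of title numbers; the tests of low-count genes, of genes with at least 100 counts and of samples high for both BK probes were written down before their results. Splits of the discovery samples of each comparison into groups of the same sizes tested the counts of called genes. In all 7 comparisons 1 of 100 splits, the real one, gave as many called genes: the real counts were 172 for AMR, 295 for TCMR and 374 for mixed rejection against no rejection, 158 for AMR against TCMR, 260 and 48 for mixed rejection against AMR and TCMR, and 115 for the departure from the sum. The highest other counts, in the same order, were 8, 0, 80, 0, 0, 2 and 29, so chance can be excluded for a free sorting of single samples. These splits do not keep the runs of title numbers, of which the groups of a pair share 1 to 8 of 16. With labels shuffled only within runs, the block in the fit and only the compared groups, the real counts were 278, 387, 306, 178, 222, 2 and 265 genes, which 1 of 100 splits, the real one, reached in 6 comparisons and 2 of 100 in mixed rejection against TCMR, with highest other counts of 174, 3, 26, 135, 20, 7 and 1. Chance within runs can be excluded for the pairwise comparisons among the 6, each taken alone and not adjusted over the 7. For AMR against TCMR this rests on the 10 AMR and 23 TCMR samples of a single run. For the departure from the sum all 4 groups were in the fit and were shuffled, which removes the AMR and TCMR changes too. Neither the free splits nor these therefore test additivity. The 2 genes between mixed rejection and TCMR lie below the highest other count. Samples in runs that hold 1 group of a pair add nothing to its differences within runs, so differences between runs stay open for them.

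Lists called by camera at the preset correlation were less specific, since random splits called a median of 5 to 7 of the 25 lists. In discovery the real counts, in the same order of comparisons, were 13, 15, 15, 11, 15, 5 and 14, which 4, 7, 2, 15, 2, 64 and 3 of 100 splits reached, with highest other counts of 14, 19, 15, 13, 15, 14 and 14. These are under 5 of 100 for AMR against no rejection, mixed rejection against no rejection, mixed rejection against AMR and the departure from the sum, each taken alone and not adjusted over the 7 comparisons, although the highest other count was as high as the real one or higher in each. Chance cannot be excluded for TCMR against no rejection, AMR against TCMR or mixed rejection against TCMR. Each list's median less the median of all targets was a sharper test. In discovery under 5 of 100 splits reached the real value for 19, 22, 20, 23, 24, 10 and 16 of the 25 lists, and in validation for 0 in each comparison. In AMR against no rejection the type I interferon (65 of 100), tubular (67), chemokine (47), B cell (46), mast cell (27) and toll-like receptor (27) medians were reached by chance.

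In the validation cohort the real split called 0 genes in each of the 7 comparisons, a count that 100 of 100 splits reach in any event, so the splits decide nothing about these counts. The highest other counts were 82, 2, 5, 7, 4, 266 and 311 genes. The median of the other counts was 0, and single splits with 266 or 311 genes may come from correlated genes in a small group or from a structure of the samples, which was not tested. Camera called 6, 11, 9, 6, 8, 11 and 11 lists with the deposited labels, and 62, 13, 29, 54, 41, 19 and 10 of 100 splits reached these counts, with highest other counts of 15, 17, 14, 16, 15, 16 and 15, so chance cannot be excluded for any of them.

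The second pattern weighed is that nearly all called genes were higher in rejection, 288 of 295 in TCMR. Larger scaling factors in rejection samples do not account for all of it: with the log2 scaling factor as a covariate 263 genes were called, 255 higher and 8 lower, although re-centring on the median of all targets left 153 higher and 119 lower and quantile normalization 136 and 95. Background counts raised together with the scaling may add to the changes of low-count genes, since the 139 genes with a median under 20 counts in discovery rose by 0.27 more than the others (0.51 against 0.23, bootstrap interval of the difference 0.13 to 0.39), and outside the leukocyte lists the values were 0.36 and 0.10. Background does not account for genes with a median of at least 100 counts, of which 113 of 379 were higher and 2 lower in TCMR. A biological explanation, leukocytes entering the graft, stays open as a hypothesis, since 138 of 172 leukocyte list genes (80.2%) and 150 of 586 other targets (25.6%) were higher.

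The third pattern weighed is that both BK virus probes were high in no-rejection samples alone, above thresholds set as the top 5% of those samples, while VP1 levels in some rejection samples lay just under the threshold. A raised probe background in runs of samples is argued against, since the 86 other no-rejection samples in the same runs of 100 title numbers had medians 5.44 (large T) and 6.38 (VP1) log2 below the thresholds (bootstrap interval of the smaller distance 4.93 to 6.11). The 13 samples high for both probes lay in 3 of the 12 runs with no-rejection samples, so carry-over between neighbouring samples stays open, as untested. A candidate explanation is BK transcripts in a few no-rejection biopsies, since 13 of the 18 samples in the top 5% of one probe were in the top 5% of the other, where 0.910 would be if the probes were unrelated (Fisher's exact test, two-sided, p = 3.61e-16). The labels give no virus status, so no biological explanation was tested further.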
